A study of Mus musculus with 4 samples.

How the data were processed

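Total RNA of 2 sub-lines of the mouse mammary carcinoma line 4T1, named 4T1-A and 4T1-S, was measured on 4 one-colour Agilent expression arrays, 2 per sub-line. Per the labels' protocols, RNA was purified on spin columns and labelled with Cy3 after linear amplification. The labels do not say whether the 2 arrays of a sub-line came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Per the file headers, all 4 arrays lay on 1 slide and were read in 1 scan, with 4T1-A at positions 1 and 2 and 4T1-S at positions 3 and 4. Slide position and sub-line therefore cannot be told apart.

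Per the file headers and the submitters' processing notes, spot intensity values were extracted with Agilent Feature Extraction 9.1. The processed intensity is, per the file headers, background-subtracted and spatially detrended, with surrogate values in place of low signals, and it is not scaled between arrays. The file of 4T1-A replicate 1 holds intensities to 3 significant digits where the others hold 7, and 47 of its gene names differ from those of the other files, in the way a spreadsheet rewrites dates. Gene names were therefore taken from the file of 4T1-S replicate 2. The deposited series table holds a linear ratio, the processed intensity divided by the array's 75th percentile to 3 decimals. This was found from the values, since no header gives its scale, and its column medians were 0.078, 0.076, 0.098 and 0.091 in the order 4T1-A replicates 1 and 2 and 4T1-S replicates 1 and 2.

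Each array held 43379 spots other than controls. The percent of these spots well above background was 54.9 and 56.3 in 4T1-A and 59.2 and 58.2 in 4T1-S, and at most 1 spot per array was saturated. The 75th percentile of the processed intensity was 467.5 and 577 in 4T1-A and 405 and 498 in 4T1-S. The median coefficient of variation of probes spotted more than once lay between 9.33 and 11.4 percent. The number of arrays limits the precision of every value.

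The values analysed were log2 of the processed intensity minus the array's 75th percentile of it over spots other than controls. Between 5 and 9 spots per array with an outlier flag were left out, and spots of the same probe were averaged. Of 41174 probes, 22951 were named through a RefSeq accession and 9768 through a current or older symbol in a table of assembly GRCm38.p6, and 8455 kept the name in the file. The array files name no genome build, so chromosome names are those of that table and no coordinates are given. Each of 27670 gene names was represented by its probe with the highest mean over all arrays. Genes were tested where that probe was well above background on both arrays of at least 1 sub-line, which left 16170 genes, of which 14206 were above background on all 4 arrays.

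The sub-lines were compared with limma 3.58.1 (lmFit and eBayes, 2-sided, residual degrees of freedom 2, prior degrees of freedom 5.71) in R 4.3.3 with the package data.table (version 1.17.8). Differences are 4T1-S minus 4T1-A on the log2 scale with their standard error (SE), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Where a probe was not well above background on either array of a sub-line, the fold is given as a lower bound, written as at least. It is the brighter sub-line's mean against the dimmer sub-line's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. The bound makes no allowance for the spread between arrays. Where the probe's own signal was the higher on both arrays, it equals the measured fold, as for Il27ra, H2-Ab1 and Pramel1. A total of 36 gene lists were fixed before the data were examined, and the 34 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01. With an estimated correlation 0 lists passed. Limma's fry, run beside it, passed 1 list in a given direction and 25 in either direction. Camera sets a list against all genes tested, whose median difference was 0.13.

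The genes named were fixed by rule before the data were examined. They are the 10 largest rises and the 10 largest falls among genes above background on all arrays, the 5 largest bounds per direction among genes above background in only 1 sub-line, up to 2 rises and 2 falls of at least 2-fold per list or else its brightest member, and 12 genes of general interest. Some genes that the rule picked or that a count includes are not reported here. The following were named outside the rule, after their values were seen: Ccl5, Cxcl10, Rsad2, Usp18, Irf7, Isg15, Cldn4, Cldn7, Krt17, Mylk, Hmgcs1, Spi1, Pramel1, Magea8, Ptges, Dusp6, Ei24, Cgas, Aim2, Nectin2, Raet1a, Postn, Gsta4, Kitl, Notch4, Kdm5d, Ccl4, Oas1f and Oas1b.

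The procedure was tested on data simulated for 16170 genes in the comparison of 4T1-S with 4T1-A, with 200 genes changed and a list of 28 members moved 2-fold. With the residual variances observed in these arrays, 0% of the genes changed 2-fold and 41% of those changed 4-fold were recovered, with 2 false calls among 43. That fell short of the recovery aimed for, and a second simulation, chosen after that outcome, drew variances from limma's fitted prior. It recovered 14% and 91%, with 4 false calls among 109. The moved list passed camera in both simulations and was missed with an estimated correlation, at adjusted p = 0.143 and adjusted p = 0.127. With so few genes changed, the adjustment is stricter than in the data, where 1128 genes passed. These recoveries therefore do not give the share missed there. In the data, 716 of the 840 genes with a measured difference of at least 2-fold passed. True changes can still be missing from the calls.

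The alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter on background, a filter on all 4 arrays, the mean of a gene's probes, the series table, an intensity trend with robust fitting, the replicate number as a block, leaving out each array in turn, and keeping spots with an outlier flag. Spike-in scaling, centring on the genes tested and cyclic loess were added after seeing the data.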

Results

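Transcript levels were measured in 4T1-A and 4T1-S, a pair of sub-lines derived from 4T1, a mammary carcinoma line of BALB/c mice. The title of the series describes 4T1-S as strongly immunogenic, so the comparison asks which transcripts distinguish it from 4T1-A. Each sub-line was represented by 2 arrays, on which between 54.9 and 59.2 percent of the spots were well above background. Over 16170 genes, replicate arrays correlated at r = 0.992 in 4T1-A and r = 0.993 in 4T1-S, across genes that are not independent replicates. The SD of the log2 difference between arrays was 0.38 and 0.37 within the sub-lines and between 0.62 and 0.72 across them.

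By limma's camera test at a preset correlation, genes induced by interferon and chemokine genes were higher in 4T1-S as lists, and genes of epithelial junctions and of basal mammary cells were lower. With an estimated correlation 0 lists passed, and limma's fry passed none of these (adjusted p between 0.0573 and 0.0888). The version with an estimated correlation cannot decide here or below, since it also missed the list moved 2-fold in both simulations. The basal list was lost with it at an estimate of -0.05, below the preset 0.01. Without 4T1-S replicate 2 the median of the basal list turned from -0.75 to 0.09. The largest rise among genes above background on all arrays was that of Kif21b, a kinesin motor (4.41 ± 0.30 on the log2 scale, SE, n = 2 arrays per sub-line), followed by Cyp1b1, a cytochrome P450 enzyme (3.95 ± 0.20), and Cmpk2, a mitochondrial nucleotide kinase induced by interferon (3.38 ± 0.34). The largest falls were those of Lcp1, an actin-bundling protein of leukocytes and many carcinoma cells (-6.51 ± 0.19, 90.9-fold), and Sfrp1, a secreted Wnt antagonist (-5.63 ± 0.19, 49.5-fold). Epcam, an epithelial adhesion molecule, was 13.8-fold lower (-3.78 ± 0.21), and Serpinb5, an epithelial serpin, was 23.7-fold lower (-4.57 ± 0.23). The adjusted p was 1.69e-04 for Kif21b, 1.05e-05 for Lcp1 and 5.61e-05 for Epcam.

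The other rises among the 10 largest ranged from 2.97 ± 0.28 for Ecscr to 3.32 ± 0.21 for Rtn4rl1. They included the potassium channel gene Kcnj4 (3.32 ± 0.18), the integrin chain Itgb7 (3.20 ± 0.43), the secreted serpin Serpinf1 (3.17 ± 0.36), the matrix protein Thbs3 (3.08 ± 0.23) and the monocyte chemoattractant Ccl2 (7.98-fold). Without 4T1-S replicate 2 the call of Itgb7 was lost, at adjusted p = 0.0646, and with no filter on background those of Itgb7 (0.0849) and Serpinf1 (0.0623). The other falls among the 10 largest were those of Nipal2 (-4.61 ± 0.21), Evpl, which encodes envoplakin of the cornified envelope (-4.25 ± 0.33), Bspry (-4.05 ± 0.19), Mid2 (-4.0 ± 0.25), Rab19 (-3.97 ± 0.20) and Htr5b (-3.91 ± 0.20). Probes of a gene did not always give the same size. A second probe gave -3.72 for Lcp1, -0.56 for Sfrp1, -0.74 for Evpl and 1.63 for Cmpk2.

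In all, 1128 of the 16170 genes passed at an adjusted p under 0.05, of which 641 were higher and 487 lower in 4T1-S. Measured differences of at least 2-fold numbered 716, with 335 higher and 381 lower, including genes whose probe was not above background on every array. Among genes above background on all arrays, differences of at least 2-fold passed for 220 genes higher and 244 lower, of at least 4-fold for 38 and 68, and of at least 16-fold for 1 and 6. The split between directions moved with the scaling. It was 189 higher and 881 lower with scaling to the median, 266 and 464 with quantile normalization and 251 and 535 with cyclic loess. Spike-in scaling gave 89 and 204 with a nearly unchanged median difference (0.125), since it mainly widened the spread between replicates. The median difference of all genes tested was 0.13, and it was -0.16 with scaling to the median, so small differences are relative to that shift. Without 4T1-A replicate 2 the count was 2345, and it was 380 without 4T1-S replicate 1 and 303 without 4T1-S replicate 2. For changes of at least 2-fold these counts were 1395, 380 and 303. Calls of single genes also moved with other processing, meaning no filter on background, spike-in scaling, normexp, quantile normalization, scaling to the median, cyclic loess, the mean of a gene's probes, an intensity trend with robust fitting, the filter on all 4 arrays, centring on the genes tested and keeping spots with an outlier flag.

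**Figure D1:**
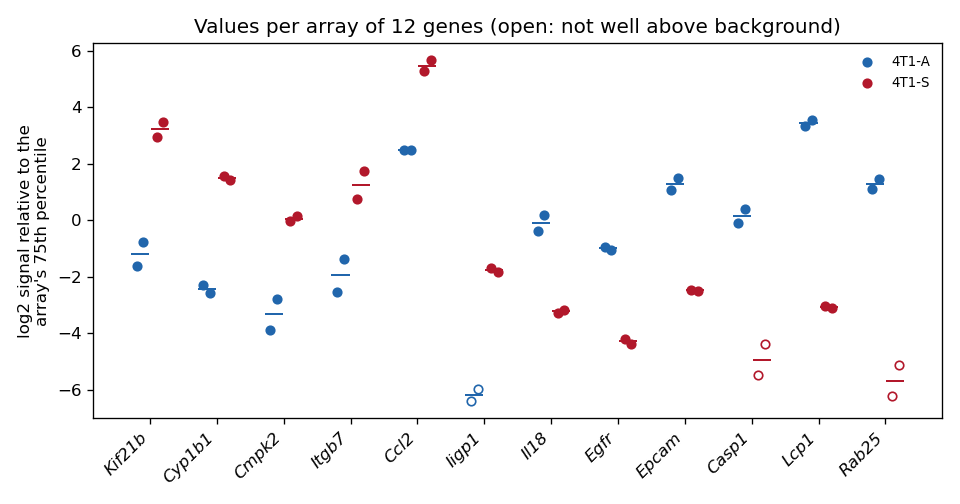
Normalised log2 signal relative to each array's 75th percentile for 12 genes in the 2 arrays of 4T1-A (blue) and of 4T1-S (red), with each point an array, each line the mean of a sub-line, and open points where the probe was not well above background on either array. The arrays of 4T1-S lie above those of 4T1-A for the first 6 genes, from Kif21b to Iigp1, and below them for the other 6, from Il18 to Rab25.

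Of 35 tested interferon-stimulated genes, 18 rose, 0 fell and 17 did not pass, and 23 rose when adjusted over the list alone. The median difference was 1.12. Iigp1, an immunity-related GTPase, was at least 5.90-fold higher in 4T1-S, and Oas2, a sensor of double-stranded RNA, at least 5.07-fold. Both were not well above background in 4T1-A. Rsad2, which encodes viperin, rose by 2.95, the deconjugating enzyme Usp18 by 2.94, the transcription factor Irf7 by 2.02 and the ubiquitin-like modifier Isg15 by 1.21. The list passed limma's camera test (adjusted p = 2.97e-10), with adjusted p = 0.688 with an estimated correlation and 0.0888 with fry. The call of Isg15 was lost with scaling to the median (adjusted p = 0.0623) and without 4T1-A replicate 1, 4T1-S replicate 1 or 4T1-S replicate 2, at adjusted p = 0.0510, 0.135 and 0.125. Other processing also ended those of Isg15, Irf7 and Usp18.

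Chemokine genes were higher as a group, with 8 of 16 tested members risen, 0 fallen and 8 not passed, and 10 risen when adjusted over the list alone. Ccl9 was at least 7.81-fold higher in 4T1-S and not well above background in 4T1-A. Ccl2 rose as given above. Ccl5, which attracts T cells, rose by 2.43, Cxcl10, an interferon-induced ligand of Cxcr3, by 2.14, and Ccl20 by 2.14 ± 0.36. Cxcl1, a neutrophil chemoattractant, differed by -0.59 ± 0.25 and did not pass (adjusted p = 0.165). Camera gave the list adjusted p = 1.22e-04, and adjusted p = 0.580 with an estimated correlation and 0.0573 with fry. The call of Ccl20 was lost without 4T1-S replicate 2 (adjusted p = 0.0692) and with normexp (0.0525), and with no filter on background Ccl20 (0.109) and Ccl5 (0.0545) lost theirs.

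Among 23 tested genes of innate sensing, 4 rose, 2 fell and 17 did not pass, against 6 and 4 when adjusted over the list alone (camera adjusted p = 0.689). Casp1, the protease that matures interleukin-1 family cytokines, was at least 19.4-fold lower in 4T1-S, where it was not well above background. The peptidoglycan sensor Nod1 fell by 1.45 ± 0.19. The nucleic acid sensors Zbp1 (1.44 ± 0.22) and Cgas (0.91) and the lipopolysaccharide co-receptor Cd14 (1.21 ± 0.18) rose, and the DNA sensor Aim2 was at least 1.55-fold higher and not well above background in 4T1-A. Of 16 tested cytokines and myeloid growth factors, 2 rose, 3 fell and 11 did not pass, against 3 and 3 when adjusted over the list alone (camera adjusted p = 0.229). Il18, a substrate of Casp1, fell 8.78-fold (-3.13 ± 0.23). Il1a fell by 1.55 ± 0.22, with 1 of 2 4T1-S arrays above background, and Kitl fell by 0.87. Vegfa rose by 1.05 ± 0.24, and Il1rn, the interleukin-1 receptor antagonist, was at least 1.80-fold higher. Csf2 (-0.35 ± 0.27) and Csf3 (-0.46 ± 0.31), growth factors of myeloid cells, did not pass. Leaving out 4T1-S replicate 2 ended the calls of Zbp1 (adjusted p = 0.102), Cd14 (0.0770), Cgas (0.192), Aim2 (0.155), Il1a (0.0742), Kitl (0.129), Vegfa (0.203) and Il1rn (0.124). Leaving out 4T1-S replicate 1 ended those of Zbp1 (0.0841), Cd14 (0.0779), Cgas (0.100), Aim2 (0.135), Nod1 (0.0585), Kitl (0.198), Vegfa (0.112) and Il1rn (0.102). Without 4T1-A replicate 1 the calls of Cgas (0.101), Aim2 (0.109) and Vegfa (0.130) were lost, and without 4T1-A replicate 2 that of Kitl (0.0642). Other processing, in at least 1 setting each, ended the calls of Zbp1, Cd14, Aim2, Cgas, Il1a, Il1rn, Kitl, Nod1 and Vegfa. The cytokine list passed camera as lower without 4T1-A replicate 1 (adjusted p = 0.0128) and with no filter on background (0.0230).

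No difference was detected in MHC class I antigen processing, where limma called 0 of 19 tested members over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.493). At an unadjusted p under 0.05, 2 were higher and 0 lower. B2m, the light chain of class I molecules, differed by 0.04 ± 0.20 (95% interval -0.43 to 0.51), the heavy chains H2-K1 and H2-D1 by 0.21 ± 0.19 and 0.06 ± 0.24, and the chaperone Canx by -0.04 ± 0.19. Of 5 tested genes of MHC class II presentation, 1 fell and 4 did not pass, against 2 when adjusted over the list alone (camera adjusted p = 0.229). That gene was H2-Ab1, whose brightest probe measured 2.45-fold lower in 4T1-S and was not well above background there. Another of its probes gave 0.16. The mean of its probes gave -0.31 and ended the call (adjusted p = 0.277), as did normexp (0.139) and spike-in scaling (0.324). Its call was lost without 4T1-S replicate 1 (adjusted p = 0.0618) or replicate 2 (0.0742). Cd274, which encodes PD-L1, was not well above background on any array.

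Ligands of lymphocyte receptors moved both ways, with 4 of 14 tested members of the co-stimulation list risen, 3 fallen and 7 not passed, and 4 and 3 when adjusted over the list alone (camera adjusted p = 0.598). The NKG2D ligands Ulbp1 (-1.79 ± 0.22), Raet1e (-1.18 ± 0.21) and Raet1a (-1.06) fell, but Raet1a differed by -0.22 with the mean of its probes (adjusted p = 0.607) and by -0.38 with normexp (0.137). The adhesion molecule Icam1 (1.55 ± 0.19), the adhesion receptor Nectin2 (1.31) and the death receptor Fas (1.30 ± 0.20) rose, and the complement regulator Cd55 was at least 1.58-fold higher. Of 17 tested genes of immune suppression, 3 rose, 0 fell and 14 did not pass, with 3 risen when adjusted over the list alone (camera adjusted p = 0.446). They were Tgfb2 (1.99 ± 0.19), the galectin Lgals9 (1.40 ± 0.21) and the prostaglandin E synthase Ptges (1.17). Of 12 tested alarmins, 0 rose, Il1a fell and 11 did not pass, with 1 fallen when adjusted over the list alone (camera adjusted p = 0.204). Of 17 tested NF-kappaB targets, 2 rose, Ccl20 and Icam1, 0 fell and 15 did not pass, with 3 risen when adjusted over the list alone (camera adjusted p = 0.495). Without 4T1-S replicate 2 the calls of Raet1e (adjusted p = 0.132), Raet1a (0.160), Icam1 (0.0570), Nectin2 (0.0855), Fas (0.108), Cd55 (0.0581), Lgals9 (0.0972), Ptges (0.118), Ccl20 (0.0692) and Il1a (0.0742) were lost. Without 4T1-S replicate 1 those of Raet1e (0.0667), Raet1a (0.173), Nectin2 (0.0596), Cd55 (0.0667) and Ptges (0.122) were lost, and without 4T1-A replicate 2 that of Raet1a (0.0621). Other processing ended those of Ulbp1, Raet1a, Raet1e, Icam1, Nectin2, Fas, Cd55, Lgals9, Ptges, Ccl20 and Il1a.

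Of 29 tested members of the list of epithelial junctions and keratins, 0 rose, 10 fell and 19 did not pass, and 16 fell when adjusted over the list alone. Rab25, an epithelial trafficking GTPase, was at least 42.4-fold lower and not well above background in 4T1-S. The tight junction genes Cldn7 and Cldn4 fell by 2.82 and 2.65, and the keratin Krt19 fell 6.12-fold. E-cadherin, encoded by Cdh1, fell 2.15-fold (-1.11 ± 0.18, adjusted p = 0.0131). Camera gave the list adjusted p = 3.12e-12, and adjusted p = 0.580 with an estimated correlation and 0.0573 with fry. The call of Cdh1 was lost without 4T1-S replicate 1 (adjusted p = 0.102) or replicate 2 (0.0969), and other processing ended those of Cdh1 and Krt19.

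**Figure D2:**
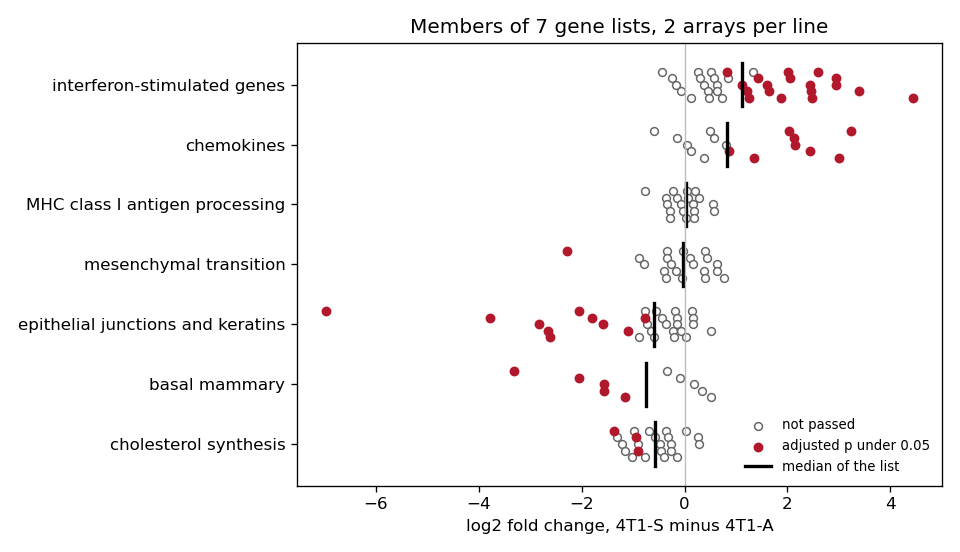
Log2 difference of each tested member of 7 gene lists, 4T1-S minus 4T1-A (2 arrays per sub-line), with filled points for members that passed, open points for the others and a bar at the list's median. Points for genes not well above background in a sub-line show the measured difference, not the bound. The medians lie at 1.12 for interferon-stimulated genes and -0.59 for epithelial junctions and keratins, while the members of MHC class I antigen processing lie between -0.76 and 0.57.

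Of 10 tested basal mammary genes, 0 rose, 5 fell and 5 did not pass, with 5 fallen when adjusted over the list alone. Egfr, the epidermal growth factor receptor, fell 9.88-fold (-3.30 ± 0.19), although its probes ranged from -3.30 to -0.10. The basal keratins Krt14 and Krt17 fell by 2.06 and 1.57, myosin light chain kinase Mylk by 1.56 and the integrin chain Itgb4 by 1.16. Camera gave adjusted p = 3.25e-04, and adjusted p = 0.580 with an estimated correlation and 0.0573 with fry. Without 4T1-S replicate 2 the list's call was lost and its median turned from -0.75 to 0.09. Of 9 tested luminal and secretory mammary genes, 0 rose, 2 fell, Krt19 and the oestrogen receptor Esr1 (-1.52 ± 0.35), and 7 did not pass, with 2 fallen when adjusted over the list alone. Camera gave adjusted p = 0.0258, adjusted p = 0.580 with an estimated correlation, 0.176 with fry and 0.189 without 4T1-S replicate 2, where its median turned from -0.19 to 0.02. The calls of Krt17, Itgb4 and Esr1 were lost without 4T1-S replicate 1 (adjusted p = 0.0986, 0.122 and 0.187) and without 4T1-S replicate 2 (0.0977, 0.0854 and 0.0678), and other processing ended those of Krt17, Krt19, Itgb4, Mylk and Esr1.

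Of 20 tested mesenchymal transition genes, limma called 0 higher and 1 lower and 19 did not pass, against 2 and 2 when adjusted over the list alone (camera adjusted p = 0.377). At an unadjusted p under 0.05, 2 were higher and 3 lower. Vim, which encodes vimentin, differed by -0.02 ± 0.22, and the transcription factor Zeb1 was at least 1.78-fold lower in 4T1-S, but it differed by -0.34 with normexp (adjusted p = 0.168) and its call was lost with an intensity trend and robust fitting (0.0544). Of 13 tested integrins, 2 rose, 1 fell and 10 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.689). Itgb7 and Itgb3 (1.40 ± 0.20) rose and Itgb4 fell. Of 21 tested collagens and basement membrane genes, 2 rose, 3 fell and 16 did not pass, against 5 and 4 when adjusted over the list alone (camera adjusted p = 0.520). Col5a1 rose by 1.63 ± 0.27, with another probe at 0.44, and Col1a1 was at least 2.59-fold higher. Among the falls were those of Lama3, a laminin chain (-2.49 ± 0.19), and periostin, encoded by Postn (-0.85), but the mean of the probes of Postn gave 0.26. Of 18 tested extracellular proteases and inhibitors, 1 rose, Mmp15 (1.55 ± 0.22), 2 fell, Mmp3 (-2.58 ± 0.18) and Mmp10 (-1.19 ± 0.19), and 15 did not pass, against 3 and 5 when adjusted over the list alone (camera adjusted p = 0.262). The protease list passed as lower with no filter on background (0.0461). Calls lost without 4T1-S replicate 2 were those of Zeb1 (adjusted p = 0.0534), Itgb7 (0.0646), Itgb4 (0.0854), Col5a1 (0.125), Col1a1 (0.0742), Postn (0.170), Mmp15 (0.0594) and Mmp10 (0.113). Without 4T1-S replicate 1 those of Itgb3 (0.0695), Itgb4 (0.122), Col5a1 (0.0595), Postn (0.181), Mmp15 (0.0695) and Mmp10 (0.0625) were lost. Without 4T1-A replicate 2 the call of Postn (0.0985) was lost, and other processing ended those of Zeb1, Itgb3, Itgb4, Itgb7, Col1a1, Col5a1, Postn, Mmp10 and Mmp15.

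Cholesterol synthesis genes were lower in 4T1-S as a group, with a median of -0.57. Of 23 tested members, 0 rose, 3 fell and 20 did not pass, and 9 fell when adjusted over the list alone. Among them, the isomerase Idi1 fell 2.57-fold (-1.36 ± 0.18) and the synthase Hmgcs1 fell by 0.95. Camera gave adjusted p = 8.55e-08, and adjusted p = 0.688 with an estimated correlation of 0.704 between members and 0.308 with fry. Of 14 tested heat shock genes, 0 rose, 2 fell and 12 did not pass, with 2 fallen when adjusted over the list alone. They were the small heat shock protein gene Hspb1 (-1.91 ± 0.18) and the co-chaperone Bag3 (-1.08 ± 0.18). The heat shock list had camera adjusted p = 0.0267, and adjusted p = 0.688 with an estimated correlation and 0.193 with fry, but 0.307 without 4T1-A replicate 1, where its median turned from -0.10 to 0.02, and 0.0589 without 4T1-S replicate 1. It was also lost with spike-in scaling (adjusted p = 0.0881) and cyclic loess (0.0818). The calls of Idi1, Hmgcs1 and Bag3 were lost without 4T1-S replicate 1 (adjusted p = 0.0587, 0.0797 and 0.0806) and replicate 2 (0.0653, 0.190 and 0.127), and that of Hmgcs1 without 4T1-A replicate 1 (0.0532), with quantile normalization (0.0512) and with the mean of its probes (0.0575). Other processing also ended those of Idi1, Hmgcs1 and Bag3.

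No difference was detected in proliferation and growth genes. None of 28 tested mitosis genes, 30 DNA replication genes, 27 oxidative phosphorylation genes and 28 ribosomal protein genes passed limma's test over all genes, and 0 passed in each when adjusted over the list alone. At an unadjusted p under 0.05 these lists had 3, 2, 1 and 0 members, and 4646 of all genes tested lay under it. The brightest member of each list differed by 0.32 ± 0.18 (Cdc20), 0.29 ± 0.18 (Mcm6), 0.12 ± 0.19 (Cox4i1) and 0.35 ± 0.20 (Rpl18). Camera gave these lists adjusted p = 0.188, 0.493, 0.540 and 0.692. The mitosis list passed as lower with normexp (adjusted p = 0.0287) and with no filter on background (0.0160).

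Of 18 tested p53 targets, 2 rose, 1 fell and 15 did not pass, against 4 and 1 when adjusted over the list alone (camera adjusted p = 0.824). Fas and the stress-induced Sesn2 (1.25 ± 0.27) rose and Ei24 (-0.98) fell. Trp53 itself differed by 0.79 ± 0.22 (adjusted p = 0.0711), and it passed without 4T1-A replicate 2 (0.00944). Of 24 tested genes of glycolysis and hypoxia, 2 rose, 2 fell and 20 did not pass, against 3 and 2 when adjusted over the list alone (camera adjusted p = 0.689). Car9, a carbonic anhydrase induced by hypoxia, fell 8.17-fold and the peptide hormone gene Adm 5.89-fold, with Adm above background on 1 of 2 4T1-S arrays. Pdk1 (1.19 ± 0.19, another probe 0.03) and Vegfa rose. Of 20 tested genes of the unfolded protein response, only Sesn2 rose, also when adjusted over the list alone, 0 fell and 19 did not pass (camera adjusted p = 0.540). The last list passed as higher without 4T1-A replicate 2, at adjusted p = 0.0280. Without 4T1-S replicate 2 the calls of Fas (adjusted p = 0.108), Sesn2 (0.155), Ei24 (0.139), Pdk1 (0.118) and Vegfa (0.203) were lost. Without 4T1-S replicate 1 those of Sesn2 (0.170), Ei24 (0.112), Pdk1 (0.0633) and Vegfa (0.112) were lost, and without 4T1-A replicate 1 those of Sesn2 (0.0902) and Vegfa (0.130). Other processing ended those of Fas, Ei24, Pdk1, Sesn2 and Vegfa.

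Of 22 tested oxidative stress genes, 2 rose, 0 fell and 20 did not pass, with 2 risen when adjusted over the list alone (camera adjusted p = 0.452). They were the glutathione transferases Gsta2, at least 1.67-fold higher, and Gsta4 (0.95). Of 20 tested immediate early genes, only Dusp6 (-0.95), a phosphatase that acts on ERK, fell, also when adjusted over the list alone, 0 rose and 19 did not pass (camera adjusted p = 0.276). The brightest, Jund, differed by 0.20 ± 0.23. The immediate early list passed as lower without 4T1-A replicate 1 (adjusted p = 2.72e-04) and without 4T1-S replicate 2 (0.0341). The calls of Gsta2, Gsta4 and Dusp6 were lost without 4T1-S replicate 1 (adjusted p = 0.108, 0.119 and 0.149) and replicate 2 (0.140, 0.144 and 0.178), and those of Gsta4 and Dusp6 without 4T1-A replicate 1 (0.0513 and 0.172). Other processing ended all 3.

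Of 18 tested genes of Wnt and Notch signalling, 2 rose, 2 fell and 14 did not pass, against 6 and 3 when adjusted over the list alone (camera adjusted p = 0.717). The ligand Wnt10a rose 4.25-fold (2.09 ± 0.20) and the receptor Notch4 by 0.84, while Sfrp1 and the Notch ligand Dll1 (-1.06 ± 0.19) fell. Of 22 tested genes of TGF-beta and BMP signalling, Tgfb2 rose, the ligand Bmp7 fell 3.88-fold (-1.96 ± 0.22) and 20 did not pass, with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.229). The calls of Notch4 and Dll1 were lost without 4T1-S replicate 1 (adjusted p = 0.169 and 0.127) and replicate 2 (0.159 and 0.112), and that of Notch4 without 4T1-A replicate 1 (0.173). Other processing ended both.

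Of 15 tested leukocyte markers, 3 rose, 0 fell and 12 did not pass, against 5 and 1 when adjusted over the list alone. They were Ncf4 (at least 2.75-fold), Cd4 (at least 2.0-fold) and Spi1 (0.86, with 1 of 2 4T1-A arrays above background). Of 8 tested testis-type and retroviral antigens, 2 rose, 0 fell and 6 did not pass, with 4 risen when adjusted over the list alone. The risen genes were Magea8 (0.91, with 1 of 2 4T1-A arrays above background) and Pramel1 (1.77-fold as measured, not well above background in 4T1-A). Spa17 of the same list differed by 0.30 ± 0.19. Camera gave the leukocyte list adjusted p = 0.0267 and the testis-type list 0.0258, and each had adjusted p = 0.580 with an estimated correlation. Fry gave 0.0634 and 0.0126. With cyclic loess they had adjusted p = 0.327 and 0.398, and with quantile normalization 0.298 each. The leukocyte list was also lost with the filter on all 4 arrays (0.368) and the testis-type list with spike-in scaling (0.170). The 4043 dimmest genes had a median difference of 0.46, against 0.05 in the 4043 brightest, and 0.11 and 0.01 with cyclic loess. The leukocyte list was lost without 4T1-S replicate 2 (adjusted p = 0.0706), and the testis-type list without any array in turn (between 0.0635 and 0.144). Without 4T1-S replicate 2 the calls of Ncf4 (0.0769), Cd4 (0.111), Spi1 (0.166), Magea8 (0.164) and Pramel1 (0.153) were lost, and without 4T1-S replicate 1 those of Ncf4 (0.0587), Spi1 (0.196), Magea8 (0.129) and Pramel1 (0.174). Without 4T1-A replicate 1 those of Magea8 (0.122) and Pramel1 (0.101) were lost, and without 4T1-A replicate 2 those of Spi1 (0.111) and Pramel1 (0.0540). Other processing ended those of Ncf4, Cd4, Spi1, Magea8 and Pramel1.

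Of 9 tested fibroblast markers, Col1a1 rose, Postn and Fbln1 fell and 6 did not pass, against 6 and 2 when adjusted over the list alone (camera adjusted p = 0.540). Fbln1, a matrix protein gene, was at least 2.23-fold lower and not well above background in 4T1-S, but with normexp it differed by -0.53 and the call was lost (adjusted p = 0.0924). Of 7 tested endothelial markers, Robo4 (1.07 ± 0.21) rose, with 1 of 2 4T1-A arrays above background, 0 fell and 6 did not pass, against 3 and 1 when adjusted over the list alone (camera adjusted p = 0.311). None of 4 tested adipocyte markers passed, also when adjusted over the list alone, and Retn differed by 0.62 ± 0.22. Of 3 tested X-inactive and Y-linked transcripts, Kdm5d was at least 1.80-fold higher, and 2 rose when adjusted over the list alone. Kdm5d differed by 0.48 to 0.69 with normexp, cyclic loess, quantile normalization and scaling to the median, which ended its call (adjusted p between 0.0883 and 0.163). Zfy1 differed by 0.22 ± 0.20. Uty was well above background on both arrays of each sub-line and did not pass. Xist, Ddx3y and Eif2s3y were not well above background on any array. The Y-linked genes were thus split in their presence calls, and whether the dim signals of Kdm5d and Uty are specific was not tested. The adipocyte and sex-linked lists were too short for camera. The calls of Col1a1 (adjusted p = 0.0742), Postn (0.170), Robo4 (0.0982) and Kdm5d (0.118) were lost without 4T1-S replicate 2. Those of Postn (0.181), Robo4 (0.149) and Kdm5d (0.173) were lost without 4T1-S replicate 1, and that of Postn without 4T1-A replicate 2 (0.0985). Other processing ended those of Col1a1, Postn, Robo4 and Kdm5d.

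The median, the mean and the camera direction of a list did not always share a sign. All 10 lists concerned had a camera direction of lower and did not pass. The median and mean were 0.02 and -0.01 for MHC class I antigen processing, 0.05 and -0.07 for innate sensing, 0.07 and -0.12 for proteases, 0.12 and -0.06 for glycolysis and hypoxia and 0.06 and -0.10 for Wnt and Notch signalling. They were both above 0 for DNA replication (0.07 and 0.02), oxidative phosphorylation (0.07 and 0.04) and ribosomal proteins (0.08 and 0.07). For integrins they were -0.13 and 0.24, and for collagens and basement membrane -0.04 and 0.03.

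Some genes were well above background in 1 sub-line alone, 648 in 4T1-S and 197 in 4T1-A. When any signal significantly above background counted as present, these numbers were 259 and 127. The 4043 dimmest genes tested had a median difference of 0.46, so dim signals lying higher in 4T1-S may add to its number, which was not tested. The largest bounds in 4T1-S after Ccl9 were those of the cytokine receptor gene Il27ra (6.66-fold, equal to its measured fold), Lrmda (at least 6.48-fold), Iigp1 and Oas2. In 4T1-A, the largest bound was that of Rab25, and others among the largest were those of the actin nucleator Cobl (at least 23.5-fold), Casp1 and the creatine kinase Ckb (at least 16-fold). The difference was called and the bound reached 2-fold for 28 genes in 4T1-S and 63 in 4T1-A. The total of 845 such genes rose to 1236 without 4T1-A replicate 1, 1688 without 4T1-A replicate 2, 1383 without 4T1-S replicate 1 and 1485 without 4T1-S replicate 2, since 1 array then decides a sub-line.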

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

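Spike-in scaling, centring on the genes tested and cyclic loess were chosen after the data were seen, and the other alternatives before. Against 1128 genes called, 511 were called with normexp, 730 with quantile normalization, 271 with no filter on background, 619 with a filter on all 4 arrays and 293 with spike-in scaling, and leaving out 1 array gave between 303 and 2345. Against 716 genes called at 2-fold or more, 333 were called with normexp, 271 with no filter, 454 with the filter on all arrays and 293 with spike-in scaling, and leaving out 1 array gave between 303 and 1395. With fewer genes above background tested, or more dim genes, the adjustment changes by construction. Spike-in scaling moved the median difference only from 0.135 to 0.125. The spike-ins lay 1.75 and 1.23 above the 75th percentile on the log2 scale in 4T1-A, and 1.84 and 1.16 in 4T1-S. That scaling therefore added a constant gap between the replicates of each sub-line, which widens their spread. Leaving out 1 array leaves 1 array in its sub-line, so the spread then comes from the other sub-line alone. A call can then be lost at nearly the same size. Cdh1 was at -1.05 and -1.16 without 4T1-S replicates 1 and 2, against -1.11 with all arrays. Other sizes moved, as for Esr1, at -1.08 and -1.97 against -1.52. For the remaining alternatives the cause was not tested. Between 6 and 12 lists passed camera, against 9, and 0 with an estimated correlation. The 845 genes above background in only 1 sub-line became 386 when any signal significantly above background counted as present, and between 1236 and 1688 without 1 array. The mean SD of log2 differences between arrays of different sub-lines was 0.655, and 0.453 with normexp.

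The replicate number as a block gave 3706 calls, with all 1128 among them. Deviations of replicate 2 from replicate 1 correlated at 0.42 between the sub-lines, but with 2 pairs and no label tying the arrays together, the number is not treated as a pairing. Among the named genes it changed the call of Trp53 alone, which passed, and it left 9 lists.

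Of 104 called genes picked by the rule or named outside it, 43 kept the call under every alternative that tested them and 61 lost it under at least 1 of 17, including 36 of the 75 picked by the rule. With genes not called included, 1738 of 2045 values kept direction and side of the threshold, 303 were weaker and 3 stronger. The weaker ones included 55 with no filter on background, 50 and 43 without 4T1-S replicates 2 and 1, 46 with spike-in scaling and 29 with normexp. With normexp, whose offset of 50 draws the differences of dim genes toward 0, 23 of 24 genes with a lower bound had a fold below it by over 1 percent, and so had 7 with the mean of probes, 6 each with scaling to the median and cyclic loess, 4 with quantile normalization and up to 3 without 1 array. The bounds therefore hold for the processing used. The only reversal was Postn, at 0.26 with the mean of its probes. Among the lists, the interferon-stimulated median stayed between 0.83 and 1.29, the epithelial median between -0.88 and -0.34 and the cholesterol median between -0.86 and -0.28. Signal over background limits the dim genes.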

Other observations

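Of the tests that this section adds, only that of chromosome gain or loss was fixed before its result was seen. The tests of gene families, dim genes, leukocytes, scaling, interferon transcription, dilution and a mesenchymal program were chosen afterwards. Results of the gene lists cited below come from the lists fixed before the data were examined. Grouping genes by the root of their symbol gave 399 families with camera tests at the preset correlation. Fry and an estimated correlation were not run on these families. Ccl chemokines (7 of 13 rose, adjusted p = 6.14e-04) and Oas genes (5 of 8 rose, median 1.58, adjusted p = 6.14e-04) were higher in 4T1-S. Both families share members with the chemokine and interferon-stimulated lists, so they add no separate support to them. Risen members outside those lists included the monocyte and T cell attractant Ccl4 (at least 4.51-fold higher), Oas1f (1.77 ± 0.23) and Oas1b (at least 1.24-fold higher). Ccl4 and Oas1b were not well above background in 4T1-A. Without 4T1-S replicate 1 or 2 the adjusted p was 0.0654 or 0.0590 for Ccl4 and 0.0707 or 0.0724 for Oas1b, whose call was also lost with normexp (0.0698) and spike-in scaling (0.235). With no filter on background the calls of Ccl4 (0.0810), Oas1f (0.0624) and Oas1b (0.0623) were lost. Olfactory receptors (99 tested, median 0.42, adjusted p = 9.32e-04) and vomeronasal receptors (18 tested, median 0.60, adjusted p = 0.00498) also passed, but not after cyclic loess (adjusted p = 0.737 and 0.304), whereas the Ccl and Oas families did (8.21e-04 and 2.49e-04).

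For the rise of interferon-stimulated genes in 4T1-S, leukocytes as the direct source of these transcripts stay undecided. The median signal rise of Ptprc, Laptm5, Coro1a, Tyrobp and Fcer1g was compared with that of the 18 interferon-stimulated genes called higher. It was 2.70 percent of it on the higher of both 4T1-S arrays and 1.25 percent on the other. The 18 genes were picked because they rose, and the ratio that leukocytes themselves would give was not measured. The ratio does not address any other effect of leukocytes in the culture. Laptm5 and Tyrobp were not well above background on any array, while Coro1a and Fcer1g were on all 4 arrays. Ptprc was well above background on 1 of 2 4T1-S arrays and on 0 4T1-A arrays. The list of leukocyte markers passed camera as higher (median 0.42, adjusted p = 0.0267). It did not pass with an estimated correlation (adjusted p = 0.580), with fry (0.0634) or after cyclic loess (0.327). Nor did it pass with quantile normalization (0.298), with the filter on all 4 arrays (0.368) or without 4T1-S replicate 2 (median 0.46). Scaling, background correction or probe choice is argued against for the alternatives tried, since the lowest median of the list over them was 0.83, with normexp. Whether the 4T1-S cells transcribe interferon stays open: 0 interferon genes above background on both 4T1-S arrays were called higher, but 5 of the 15 with a probe were above background on no array and Ifnb1 was on 1 of 2 4T1-S arrays. A difference of the sub-line itself and an effect of slide position both stay open as untested, since the design does not separate them.

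Fold changes also differed by chromosome (assignment from GRCm38.p6). Of 20 chromosomes, 17 had a median with an adjusted p under 0.05 against shuffled genes, so the p is not particular to a few, and 2 of them also lay more than 0.2 from the median of all genes, a limit fixed before the test. The median of 631 genes on chromosome 10 lay -0.294 from that of all genes, and that of 470 genes on chromosome 14 lay 0.293 above it. Each had a 2-sided permutation p = 1e-04, the smallest that 10000 shuffles of genes over 20 chromosomes can give (adjusted p = 2.22e-04). On these chromosomes 24.2 and 81.3 percent of genes lay above the median of all genes. The shuffles treat genes as independent, so this p measures no spread between arrays or cultures. Dim genes lying higher in 4T1-S are argued against as the whole cause, since chromosome 14 still lay 0.266 above after cyclic loess and chromosome 10 lay -0.257 from it. The shift ran through the first, middle and last part of each chromosome in gene order (-0.37, -0.27 and -0.26 from the median of all genes on 10, and 0.21, 0.21 and 0.46 on 14). A gain or loss of these chromosomes in 1 sub-line, or in part of its cells, may account for it and was not measured on DNA.

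The fall of epithelial genes in 4T1-S was uneven. Of 29 tested members, 8 had a 95% interval wholly below -1 and 13 wholly above it, which argues against dilution by cells without any of these transcripts, in a test and with limits set after these counts were known. The 13 are fewer than the majority that an earlier test of dilution by cells of another type asked for, so dilution by cells that share some of these transcripts stays open. A rise of 2-fold or more is argued against for 17 of 20 tested mesenchymal transition genes, which had a 95% interval wholly below 1. Smaller rises are not excluded. A mesenchymal program already on in both sub-lines would show no rise, so this test cannot address it. The mean normalised log2 signal of Vim was 4.43 in 4T1-A and 4.41 in 4T1-S. A mesenchymal program therefore stays open beyond those limits. Over all genes 0 of the mesenchymal transition genes rose, and 2 rose when adjusted over the list alone, as at an unadjusted p under 0.05. A selective loss of epithelial transcripts in 4T1-S was not tested against that dilution.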
